A study of Danio rerio with 12 samples.

How the data were processed

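RNA was measured in zebrafish (Danio rerio) embryos of the rx3:GFP line on 1-colour (Cy3) NimbleGen Zebrafish Gene Expression 385K arrays, per the labels. There were 12 arrays in 3 groups of 4, and each array was placed in its group by its own label. The groups were control (labelled wild-type), sema6A morphant and plexinA2 morphant. The labels call the 4 arrays of a group biological replicates, and whether each came from its own clutch is not stated in the sources used here.

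Total RNA was extracted with Trizol and checked on a Bioanalyzer, and labelling was done by the array maker, per the labels' protocols. RMA (robust multi-array average, which corrects background, normalizes between arrays and summarizes probes) is named in the submitters' processing notes, without a version. The values the authors deposited are intensity values on a linear scale, from 26.3 to 42222 with no zeros, so RMA output had been returned from the log scale before deposit. RMA's background model compresses differences among dim probes, so fold changes of dim genes are understated, and its normalization fixes the overall level of each array, so a shift of all genes together cannot be seen. Array medians lay between 608 and 708. The number of arrays limits the precision of every value, and the depth measures used for sequencing do not apply.

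The table used here had 5134 rows, each an Ensembl gene identifier, and why it held these rows is not given in the sources used here. Over the 12 arrays the smallest range of any row was 0.63 on the log2 scale and the median range 1.74. Whether rows of little variation had been left out is not known here. All counts, adjusted p values and list tests therefore refer to these rows only. Symbols came from a gene name table, which matched 4349 of the 5134 rows and left 785 unnamed. Among the symbols, 112 stood on more than 1 row, and 2669 rows carried upper-case symbols that do not tell apart the paralogues a and b of a duplicated zebrafish gene. Gene names are printed as that table gives them. The genome build behind the array is not given in the sources used here, so no coordinates are printed. The rows of the targeted genes sema6a and plxna2 were not analysed here, and the planned check of their levels was not run.

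The values were transformed to log2 with no pseudocount and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings). All 12 arrays entered a single model with group as its only term and 9 residual degrees of freedom, and the prior added 9.54. Each comparison was tested two-sided with Benjamini-Hochberg adjustment over its 5134 rows, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and every adjusted p of a gene is limma's.

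Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 row per gene (the row of highest mean). Of the 16 lists, 15 are reported here. They covered the eye field and optic vesicle, semaphorins with plexins and neuropilins, other axon guidance genes, cell cycle, Notch signalling and neurogenesis, p53 and apoptosis, and interferon and innate immunity. The remaining lists covered heat shock and stress, somite segmentation, muscle, blood and endothelium, neural crest and pigment, epidermis with hatching gland and notochord, yolk and lipoproteins, and lens with placodes. Of 907 list entries, 843 matched the name table exactly, by case or without the trailing paralogue letter, and 286 were measured. The eye field list held 37 names and gave 13 measured genes, p53 47 and 24, muscle 91 and 36, and Notch 66 and 15. Names could share 1 measured gene where the paralogue letter was dropped. Some genes stood on more than 1 list. The 48 tests were adjusted together. Camera with an estimated correlation and fry, which asks only whether the genes of a list move one way on balance, were run as alternatives. A list score was the mean deviation of its genes from their means over the 12 arrays, on the log2 scale.

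Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named RASL11B and SHTN1, because later work of the same field studied them downstream of Sema6A and PlexinA2. Whether that work drew on these arrays is not known here, so their changes are no independent check. It also took, per morphant, the 12 largest rises and 12 largest falls with a symbol among called genes whose 4 morphant arrays all lay on one side of the 4 control arrays. Between the morphants it took the 6 largest in each direction, for both morphants the 10 genes with the smallest larger p, and per list up to 4 genes of smallest p in each morphant comparison. The rule gave 137 rows, and the text names only part of them. Genes said to be chosen after their values were seen fall outside it.

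The alternatives were the replicate number as a block, fits of only the groups compared, the dimmest 25 percent of rows left out, quantile normalization, median-centred arrays, a trended and robust variance, array weights, log2(value + 16), 1 row per symbol, and leaving out each array in turn. A fit without the 2 arrays of lowest mean rank correlation was added after seeing the data. Correlations and overlaps between the morphant comparisons, which share their controls, were set beside 100 simulations of unchanged groups built from the residuals and beside the 6 ways of giving each comparison its own 2 controls.

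The code was tested on simulated data of 5134 rows with 200 changed, in 1 run per comparison. The simulated noise was independent between rows and arrays, with the same spread of a row in every array. For sema6A against control it recovered 36.8% of changes of 1 on the log2 scale, 86.8% of changes of 2 and 96.9% of changes of 3, with 7 false calls among 153. For plexinA2 against control the shares were 26.4%, 89.2% and 100%, with 11 false calls among 164. No 2 arrays shared more than 2 identical values, so no array was a copy of another.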

Results

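Embryos of the zebrafish line rx3:GFP, whose reporter is named for the eye field transcription factor gene rx3, had been injected before the first cell division with an antisense morpholino. A morpholino is an oligonucleotide that blocks the translation or splicing of its target RNA. One group received a morpholino against Sema6A, a transmembrane semaphorin, and another a morpholino against PlexinA2, a semaphorin receptor. The third group was the control, labelled wild-type, for which the labels name no injection. Its arrays are titled UIC, a short form not spelled out in the sources used here. RNA of each group was hybridised to 4 arrays. The labels give the stage both as 18 hours after fertilisation and as 18 somites reached at 25 °C. The comparisons ask which genes change when either member of this ligand and receptor pair is targeted, which change in both, and where the morphants differ.

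The mean rank correlation of an array with the other 11 lay between 0.907 and 0.932 for 10 arrays. It was 0.835 for control replicate 2 and 0.876 for sema6A replicate 1. The plexinA2 arrays were the closest to one another, with mean rank correlations within the group of 0.967 to 0.976. These were 0.903 to 0.946 for the sema6A arrays and 0.843 to 0.911 for the controls. The median residual SD was 0.47 on the log2 scale.

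Sema6A morphants had higher levels of genes of the p53 response and of the AP-1 genes FOS and FOSL1 than controls, and lower levels of an embryonic globin and a neural transcription factor. PHLDA3 (ENSDARG00000037804), a p53 target that restrains Akt, rose 12.5-fold, or 3.64 ± 0.28 on the log2 scale (SE, n = 4 per group, limma adjusted p = 2.02e-07). The initiator caspase gene casp8 (ENSDARG00000058325) rose by 3.55 ± 0.33 (adjusted p = 2.32e-06). FOS (ENSDARG00000031683), an AP-1 transcription factor gene, rose by 3.05 ± 0.30 (adjusted p = 4.89e-06). The embryonic alpha globin gene hbae1.3 (ENSDARG00000089124) fell by 2.49 ± 0.47 (adjusted p = 0.00637), and MYT1 (ENSDARG00000074030), a zinc finger factor of the nervous system, fell by 1.97 ± 0.36 (adjusted p = 0.00449).

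In all, 160 of 5134 rows passed, 102 higher and 58 lower in sema6A morphants, against 1056 at an unadjusted p under 0.05. In 143 of the 160 the 4 morphant arrays lay wholly on one side of the 4 controls. Calls were picked by p from these same arrays, so such a share, here and in the other comparisons, adds no support. The largest rises with a symbol and no overlap between the groups were si:dkey-204l11.1 (4.21), ATXN1 (3.99), PHLDA3, casp8, RBL2 (3.52) and rpz5 (3.37). They were followed by the exonuclease gene EXO5 (3.22), FOS, mat2al (2.89), GADD45A (2.85), GTPBP1 (2.84) and MFAP4 (2.73). Second rows of ATXN1 (−0.09, adjusted p = 0.910) and GTPBP1 (0.18, adjusted p = 0.783) did not pass. The largest falls by the same rule were hbae1.3, the proteasome subunit gene PSMB2 (−2.39), RFX1 (−2.26), the cytochrome c oxidase subunit gene cox6b1 (−2.16), MYT1, the water channel gene AQP1 (−1.78) and FABP7 (−1.78), a fatty acid binding protein gene of radial glia. These were followed by lgals3a (−1.77), LZTS2 (−1.75), slc38a5b (−1.71), PAPSS2 (−1.65) and FOXF1 (−1.64). A second PAPSS2 row did not pass (0.69, adjusted p = 0.224). The call of PAPSS2 was lost without sema6A replicate 2 or 3 (largest adjusted p = 0.0572), and that of LZTS2 without either of these or control replicate 1 or 2 (0.1002). AQP1 (largest adjusted p = 0.103), FABP7 (0.0808) and lgals3a (0.127) each lost theirs in 9 of the 12 fits without 1 array.

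RASL11B (ENSDARG00000015611), a Ras-like small GTPase gene named from later work on this pair, rose by 2.18 ± 0.30 in sema6A morphants (adjusted p = 0.000366). SHTN1 (ENSDARG00000039697), which encodes the neuronal polarity protein shootin, rose by 1.21 ± 0.27 (adjusted p = 0.0167), a call lost without sema6A replicate 2 or 3 (largest adjusted p = 0.0801).

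Of 24 measured genes of the p53 and apoptosis list, 10 rose, none fell and 14 did not pass in sema6A morphants. Adjusted over the list alone, 14 rose and 1 fell. The list's median was 0.77, and 22 of 24 genes were higher (camera adjusted p = 7.86e-13, and adjusted p = 0.0304 with an estimated correlation). Besides PHLDA3 and casp8, GADD45A, a growth arrest gene, rose by 2.85 ± 0.36 and bbc3, which encodes the apoptosis inducer Puma, by 2.37 ± 0.35. The other genes that rose, chosen after their values were seen, included pmaip1 (2.15), the cell cycle inhibitor gene cdkn1a (2.13), mdm2 (1.76), SESN1 (1.49) and BAX (1.35). The heat shock and stress list had 3 genes up, 0 down and 9 not passed among 12 (7 up and 1 down adjusted over the list alone). Its median was 0.93 (camera adjusted p = 0.000112, and adjusted p = 0.0661 with an estimated correlation). The 3 genes were FOS, FOSL1 (5.29-fold, adjusted p = 0.00139) and the peroxiredoxin gene prdx1 (1.39 ± 0.33, adjusted p = 0.0249), which was lost without control replicate 1 or 3 or sema6A replicate 1, 2 or 3 (largest adjusted p = 0.0811). FOS and FOSL1 are AP-1 factors rather than heat shock proteins.

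All 13 measured genes of the eye field and optic vesicle list (37 names) were lower in sema6A morphants than in controls. None passed the test alone (1 fell adjusted over the list alone). The list's median was −0.52 (camera adjusted p = 0.000517, and adjusted p = 0.0304 with an estimated correlation). Genes of small p in it were foxd1, a temporal retina marker (−1.26 ± 0.37, adjusted p = 0.0648), SIX3 (−0.63 ± 0.30, adjusted p = 0.251) and VAX1 (−0.65 ± 0.32, adjusted p = 0.258). The log2 values of foxd1 were also lower in plexinA2 morphants (10.40 to 11.05) than in controls (11.52 to 11.82). The list score was −0.48 ± 0.10 in sema6A morphants and 0.17 ± 0.18 in controls (SD, n = 4), and the ranges did not overlap.

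Blood and endothelium genes were 0 up, 3 down and 26 not passed among 29 in sema6A morphants (8 down adjusted over the list alone). The 3 were hbae1.3, the erythroid transcription factor gene gata1a (−1.59 ± 0.33, adjusted p = 0.0103) and alas2, the first enzyme of erythroid haem synthesis (−1.52 ± 0.34, adjusted p = 0.0183). The call of gata1a was lost without sema6A replicate 3 (adjusted p = 0.0522) and that of alas2 without sema6A replicate 2 (0.0572). The list's median was −0.49 (camera adjusted p = 2.12e-05, and adjusted p = 0.223 with an estimated correlation). It was −0.24 without sema6A replicate 1, which had the lowest list score (−1.16), and −0.27 without control replicate 4, which had the highest (0.71). Muscle genes were 1 up, 0 down and 35 not passed among 36 (1 up and 1 down adjusted over the list alone). The gene that rose was nebl (2.00 ± 0.41, adjusted p = 0.0101), which encodes nebulette. The muscle median was −0.67 (camera adjusted p = 8.28e-06, and adjusted p = 0.354 with an estimated correlation), and −0.34 without sema6A replicate 1 and −0.35 without control replicate 4.

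Notch and neurogenesis genes were 0 up, 2 down (MYT1 and FABP7) and 13 not passed among 15, with 3 down adjusted over the list alone. The median was −0.54 (camera adjusted p = 0.00112, and adjusted p = 0.130 with an estimated correlation). Cell cycle genes were 0 up, 1 down and 21 not passed among 22, with 3 down adjusted over the list alone. CDC6, which loads the replicative helicase, fell by 1.34 ± 0.35 (adjusted p = 0.0411), and the median was −0.25 (camera adjusted p = 0.00643, and adjusted p = 0.454 with an estimated correlation). Control replicate 2 had the lowest cell cycle score of all arrays (−0.67), and without it the list's median was −0.67. CDC6 lost its call in 9 of the 12 fits without 1 array (largest adjusted p = 0.149), and the cell cycle list was lost without control replicate 1 (0.0847).

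No member of the remaining lists reported here passed over all rows in sema6A morphants. The interferon list shifted up over 13 genes (median 0.73, 5 up adjusted over the list alone, camera adjusted p = 0.00758, and adjusted p = 0.130 with an estimated correlation). Axon guidance genes shifted down over 22 genes (median −0.23, camera adjusted p = 0.0167, and adjusted p = 0.503 with an estimated correlation). The epidermis, hatching gland and notochord list shifted down over 17 genes (median −0.44, camera adjusted p = 0.00981, and adjusted p = 0.234 with an estimated correlation). Somite segmentation genes did so over 19 (median −0.28, camera adjusted p = 0.0287, and adjusted p = 0.480 with an estimated correlation). Single arrays carried some of these: the guidance list was lost without control replicate 4 (adjusted p = 0.318), the epidermis list without sema6A replicate 1 (0.0741) or control replicate 4 (0.0534), and the somite list in 5 of 12 fits (largest 0.253, without control replicate 3). The guidance median was −0.05 without control replicate 4. The epidermis median was −0.16 without control replicate 4 and −0.26 without sema6A replicate 1, and the somite median −0.61 and −0.47. Not passed were the semaphorin and plexin list (median −0.27, adjusted p = 0.0955), neural crest (−0.16, adjusted p = 0.171), yolk (−0.17, adjusted p = 0.201) and lens (−0.29, adjusted p = 0.120). Without control replicate 4 the medians were −0.10 for semaphorins, 0.04 for neural crest and −0.12 for lens. The neural crest median was 0.08 without sema6A replicate 1, and the yolk median −0.43 without control replicate 2. Adjusted over the list alone, the 7 lists other than interferon had no gene past the threshold except 1 neural crest gene down and, in the yolk list, 1 up and 1 down.

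The count of 160 was 66 without sema6A replicate 2, 67 without sema6A replicate 3, 85 without control replicate 1 and 103 without plexinA2 replicate 4. It was 47 (38 up, 9 down) when only the control and sema6A arrays were fitted and 1407 with array weights. In the fit of only the control and sema6A arrays, RFX1, FOXF1, nebl, gata1a, alas2, LZTS2 and PAPSS2 lost their calls. So did AQP1, FABP7, lgals3a, prdx1, CDC6 and SHTN1. Among the largest falls, hbae1.3, PSMB2, cox6b1, MYT1 and slc38a5b kept theirs.

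**Figure D1:**
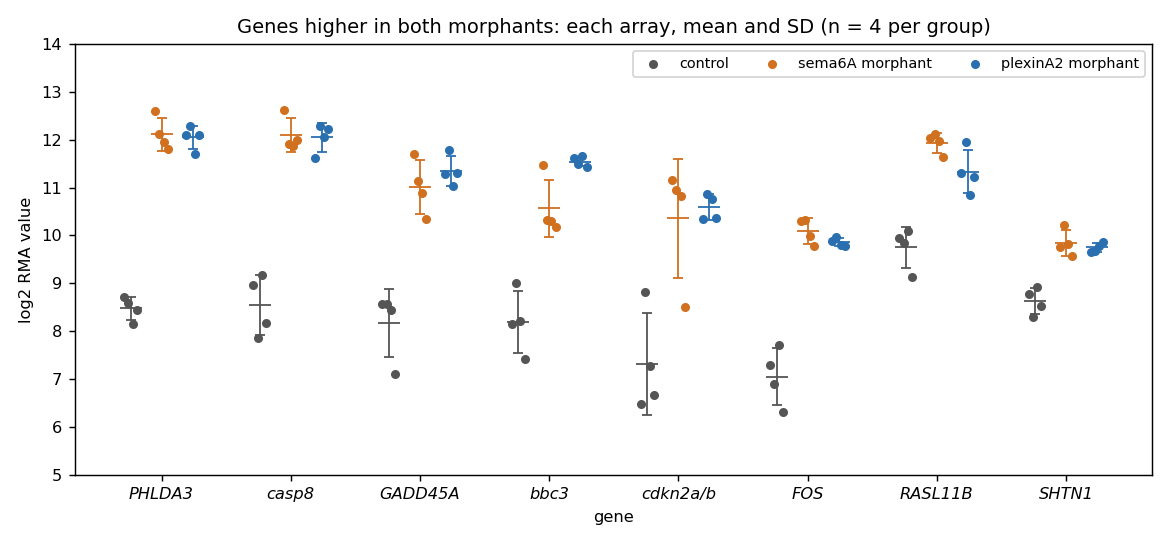
Log2 RMA value (vertical axis) of 8 genes in each array, with bars for the mean and SD of the 4 arrays per group. PHLDA3 averaged 8.47 in controls, 12.12 in sema6A morphants and 12.05 in plexinA2 morphants, and cdkn2a/b in sema6A replicate 4 (8.51) lay within the control range.

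PlexinA2 morphants also had higher p53 response genes than controls, together with genes of the interferon and innate immunity list. Here PHLDA3 rose by 3.57 ± 0.28 (SE, n = 4 per group, limma adjusted p = 2.78e-07), and bbc3 rose 10.2-fold, or by 3.35 ± 0.35 on the log2 scale (adjusted p = 7.38e-06). The retinaldehyde binding protein gene rlbp1b (ENSDARG00000045808) rose by 3.25 ± 0.28 (adjusted p = 8.58e-07). PSME2, a proteasome activator subunit gene, rose by 2.03 ± 0.33 (adjusted p = 0.00115). The maternal chromatin gene npm2b (ENSDARG00000053963) fell by 1.88 ± 0.39 (adjusted p = 0.0102), a call lost without plexinA2 replicate 2 (adjusted p = 0.0504).

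In all, 147 of 5134 rows passed, 134 higher and 13 lower in plexinA2 morphants, against 885 at an unadjusted p under 0.05. In 142 of them the groups did not overlap. The largest rises with a symbol and no overlap were si:dkey-204l11.1 (21.2-fold), ATXN1 (19.8-fold), and, on the log2 scale, MFAP4 (4.09), RBL2 (3.68), PHLDA3, casp8 (3.50), EXO5 (3.48), rpz5 (3.37), bbc3, cdkn2a/b (3.28), rlbp1b and GADD45A (3.18). The second ATXN1 row did not pass here either (0.59, adjusted p = 0.353). Below npm2b, the largest falls by the same rule were ATP1B4 (−1.40), cyp2x7 (−1.37), SRPRA (−1.35), NR0B2 (−1.33), TMED1 (−1.33), krcp (−1.32) and MAT2A (−1.26). SRPRA, a subunit gene of the signal recognition particle receptor, and NR0B2 kept their calls without any single array. ATP1B4 lost its call without plexinA2 replicate 1, 3 or 4 (largest adjusted p = 0.0883), cyp2x7 in 4 of 12 fits (0.0815), krcp in 5 (0.158), TMED1 in 6 (0.106) and MAT2A in 8 (0.204).

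RASL11B rose by 1.58 ± 0.30 in plexinA2 morphants (adjusted p = 0.00525), and SHTN1 by 1.12 ± 0.27 (adjusted p = 0.0240). The SHTN1 call was lost without control replicate 1 or without any of the 4 plexinA2 arrays (largest adjusted p = 0.1, without plexinA2 replicate 4).

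Of the 24 p53 and apoptosis genes, 11 rose, none fell and 13 did not pass in plexinA2 morphants, with 16 up and 1 down adjusted over the list alone. The median was 1.01, and 21 of 24 were higher (camera adjusted p = 6.68e-13, and adjusted p = 0.0304 with an estimated correlation). Beyond those above, the genes that rose, chosen after their values were seen, included SESN1 (2.57), cdkn1a (2.53), mdm2 (1.91), pmaip1 (1.89), CDKN1B (1.32) and BAX (1.00). Of the 13 interferon and innate immune genes, 5 rose, none fell and 8 did not pass, with 8 up adjusted over the list alone. The median was 0.79 (camera adjusted p = 4.60e-06, and adjusted p = 0.0304 with an estimated correlation). The 5 were PSME2, the inhibitor of NF-κB gene nfkbiaa (1.72 ± 0.28, adjusted p = 0.00106), isg20 (1.45 ± 0.28, adjusted p = 0.00568), the metalloproteinase gene MMP9 (1.39 ± 0.30, adjusted p = 0.0115) and the immunoproteasome gene PSMB8 (1.52 ± 0.36, adjusted p = 0.0240). MMP9 lost its call without control replicate 1 or plexinA2 replicate 4 (largest adjusted p = 0.0687).

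FOS (2.81 ± 0.30, adjusted p = 1.11e-05) and FOSL1 (2.03 ± 0.38, adjusted p = 0.00480) were the 2 of 12 heat shock and stress genes that rose in plexinA2 morphants, with 0 down, 10 not passed, and 3 up adjusted over the list alone. That list's median was 0.37 (camera adjusted p = 0.0167, and adjusted p = 0.223 with an estimated correlation), and 0.19 without control replicate 2. Of 22 axon guidance genes, epha2b, an ephrin receptor gene, rose (1.16 ± 0.30, adjusted p = 0.0452, lost in 10 of the 12 fits without 1 array, with a largest adjusted p of 0.206). The other 21 did not pass, and 1 rose adjusted over the list alone (median 0.51, camera adjusted p = 0.00447, and adjusted p = 0.454 with an estimated correlation). Of 15 semaphorins, plexins and neuropilins none passed, with none adjusted over the list alone (median 0.51, camera adjusted p = 0.0198, and adjusted p = 0.454 with an estimated correlation). Without control replicate 3 the guidance list (adjusted p = 0.0847) and the semaphorin list (0.204) were lost, the semaphorin list also without control replicate 1 (0.0847) or plexinA2 replicate 3 (0.0538), and the stress list without control replicate 4 (0.0563). The least p values among the semaphorins were those of sema3gb (0.93 ± 0.34, adjusted p = 0.173) and sema3ga (0.88 ± 0.32, adjusted p = 0.173).

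Muscle genes were 1 up (nebl, 1.79 ± 0.41, adjusted p = 0.0196), 0 down and 35 not passed among 36 in plexinA2 morphants, with 3 up adjusted over the list alone. The nebl call was lost without control replicate 1 or plexinA2 replicate 2, 3 or 4 (largest adjusted p = 0.0798). The median was 0.54 (camera adjusted p = 0.00149, and adjusted p = 0.503 with an estimated correlation), and 0.81 without control replicate 4, whose muscle score of 0.86 was the highest of all arrays. No cell cycle gene of 22 passed, over all rows or adjusted over the list alone (median −0.39, camera adjusted p = 0.00419, and adjusted p = 0.454 with an estimated correlation), and the median was −0.60 without control replicate 2 and the call was lost without control replicate 1 (0.0646). The eye field list did not pass (median 0.21, adjusted p = 0.836), nor did blood and endothelium (0.10, adjusted p = 0.947), Notch and neurogenesis (−0.04, adjusted p = 0.719, with jag2a up by 1.56 ± 0.35), somite segmentation (−0.20, adjusted p = 0.171) or neural crest (−0.07, adjusted p = 0.417). The epidermis list (0.34, adjusted p = 0.303), the yolk list (−0.27, adjusted p = 0.201) and the lens list (0.09, adjusted p = 0.845) did not pass either. Without control replicate 4 the medians were 0.18 for Notch, 0.12 for neural crest, −0.34 for somites and 0.57 for epidermis. Without control replicate 2 they were 0.09 for the eye field, −0.05 for blood, −0.12 for yolk and −0.01 for lens. In these lists jag2a was the only gene past the threshold, also adjusted over the list alone, and it was lost in 5 of 12 fits without 1 array (largest adjusted p = 0.0792). For the blood list and the Notch list the median and the camera direction or the mean differed in sign.

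The count of 147 was 92 without control replicate 1, 95 without control replicate 3 and 326 without control replicate 4. Leaving out plexinA2 replicates 1 to 4 in turn gave 96, 94, 84 and 79. It was 275 without control replicate 2 and sema6A replicate 1 together and 1629 with array weights. The share of higher calls, 91.2%, was 82.8% without control replicate 4 (270 up, 56 down), 81.5% with median-centred arrays (106 up, 24 down), 79.6% without control replicate 2 and sema6A replicate 1 (219 up, 56 down) and 62.2% with array weights (1013 up, 616 down).

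Both morphants shared raised genes, among them genes of the p53 response. Passed in both comparisons and in the same direction were 58 genes, 57 higher and 1 lower (ATP1B4, whose product sits in the nuclear membrane of muscle in mammals, −1.44 ± 0.32 and −1.40 ± 0.32), and none in opposite directions. Only 13 genes were lower in plexinA2 morphants and so open to sharing. Independent lists of these sizes would share 2.66 higher and 0.147 lower genes, and 100 simulations of unchanged groups against the same controls shared none. Unchanged groups are expected to give hardly any calls to share. The simulated result was thus near certain and does not show how many shared calls the common controls add. With the controls split so that each comparison had its own 2, the shared calls were 10 to 25 over 6 splits. The 10 genes with the strongest change in both were ATXN1, PHLDA3, RBL2, si:dkey-204l11.1, casp8, EXO5, GTPBP1, FOS, mat2al and GADD45A. For none of the 10 did the morphants differ in the direct test, with differences from −0.33 ± 0.36 (GADD45A, adjusted p = 0.559) to 0.28 ± 0.27 (GTPBP1, adjusted p = 0.510).

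Of the p53 list, 10 genes rose in both morphants, with a median difference between the morphants of −0.15. The list did not pass between the morphants (median −0.05, 0 of 24 genes past the threshold, also adjusted over the list alone, camera adjusted p = 0.845). Past the threshold in the sema6A comparison and not in the plexinA2 comparison were 102 rows, and the reverse held for 89, which is not a test of a difference. Across all rows, which are not independent replicates, the fold changes of the comparisons correlated with r = 0.413. Simulated unchanged groups gave a mean r of 0.446 (from −0.448 to 0.975), so the observed r lay well within their range. The covariance was 0.143 against a simulated mean of 0.0673, a difference of 0.0761. No spread of the simulated covariance is given here, so that difference has no stated weight. The fold changes had the same sign in 57.7% of rows, below the simulated mean of 66.6%. With split controls the mean r was 0.0932 (from −0.176 to 0.269) and the mean covariance 0.0317. The count of 58 was 38 without sema6A replicate 2, 32 when each morphant was fitted with the controls alone, and 518 with array weights, then 346 higher and 172 lower.

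**Figure D2:**
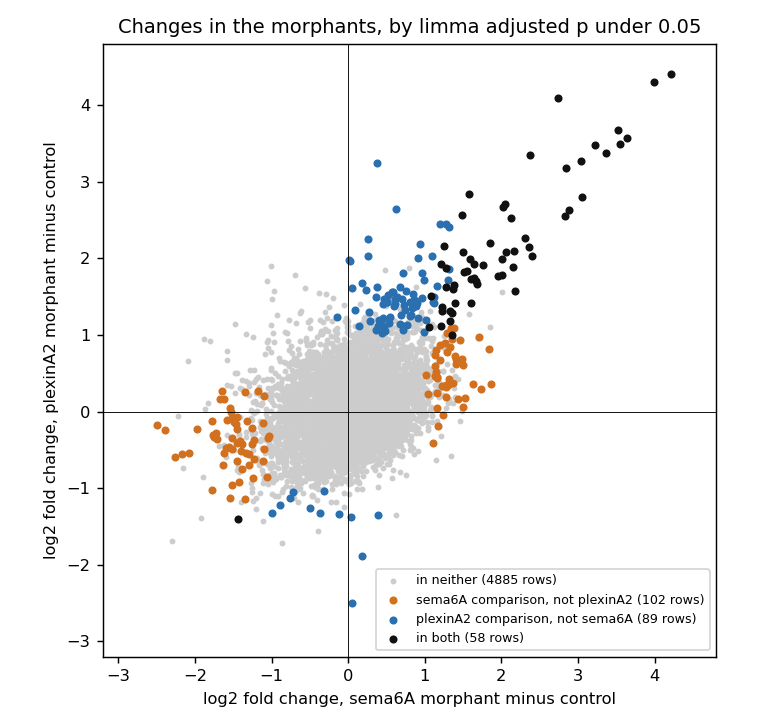
Log2 fold change against control of each of the 5134 rows in sema6A morphants (horizontal axis) and plexinA2 morphants (vertical axis), coloured by whether limma's adjusted p was under 0.05 in neither comparison (4885), sema6A (102), plexinA2 (89) or both (58). Of the 58 called in both, 57 lie at upper right, with PHLDA3 at 3.64 and 3.57, and 1 lies at lower left.

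Set directly against plexinA2 morphants, sema6A morphants had lower levels of the muscle genes XIRP2 and RYR1, of rlbp1b and of an embryonic globin, and higher levels of npm2b and SRPRA. The muscle actin-binding gene XIRP2 (ENSDARG00000071113) was 7.47-fold lower, a difference of −2.90 ± 0.52 on the log2 scale (SE, n = 4 per group, limma adjusted p = 0.0139). For rlbp1b the difference was −2.88 ± 0.28 (adjusted p = 2.62e-05), and for hbae1.3 −2.31 ± 0.47 (adjusted p = 0.0233). SRPRA was higher by 1.75 ± 0.28 (adjusted p = 0.00554) and npm2b by 2.06 ± 0.39 (adjusted p = 0.0199). XIRP2 lost its call in 3 of the 12 fits without 1 array (largest adjusted p = 0.0706). RYR1 (0.0903), hbae1.3 (0.0926) and npm2b (0.0837) each lost theirs in 5.

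In all, 88 of 5134 rows passed, 23 higher and 65 lower in sema6A morphants, against 1376 at an unadjusted p under 0.05, and in 87 of them the groups did not overlap. The share of higher calls moved from 26.1% to 43.0% with quantile normalization (158 calls), 44.5% with median-centred arrays (146 calls), 48.0% without control replicate 2 and sema6A replicate 1 (880 calls) and 50.2% with array weights (2273 calls). The other large falls were MATN4, a cartilage matrix gene (−2.83), the muscle glycogen phosphorylase gene PYGM (−2.47) and the sarcoplasmic calcium release channel gene RYR1 (−2.47). A second RYR1 row fell too (−2.13, adjusted p = 0.0199), and a second PYGM row did not pass (−1.04, adjusted p = 0.0634) although it fell against control (−1.45 ± 0.29, adjusted p = 0.00998). MATN4 and PYGM each had 1 control array, replicate 4, far above the other controls. The other large rises were brf2 (1.51), cimap1d (1.45), B3GNT9 (1.41) and cyp2x7 (1.41). MATN4 and brf2 lost their calls in 5 of the 12 fits without 1 array, and PYGM, cimap1d, B3GNT9 and cyp2x7 in 6. PSMB2 (−2.15 ± 0.31, adjusted p = 0.00234) and cox6b1 (−1.61 ± 0.33, adjusted p = 0.0239), lower than control in sema6A morphants, were lower than in plexinA2 morphants as well.

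Muscle genes were 0 up, 5 down and 31 not passed among 36 in sema6A against plexinA2 morphants, and 26 fell adjusted over the list alone. The 5 were XIRP2, RYR1, the thin filament gene NEB (−2.20 ± 0.44, adjusted p = 0.0206), the acetylcholine receptor subunit gene CHRND (−1.52 ± 0.36, adjusted p = 0.0420) and MEF2D (−1.22 ± 0.31, adjusted p = 0.0498), the last chosen after its value was seen. The median was −1.21 (camera adjusted p = 1.78e-11, and adjusted p = 0.223 with an estimated correlation). The muscle score was 0.62 ± 0.04 in plexinA2 morphants, −0.64 ± 0.80 in sema6A morphants and 0.02 ± 0.56 in controls (SD, n = 4). In sema6A replicate 1 it was −1.82, and without that array the median was −0.83. Blood and endothelium genes were 0 up, 2 down (hbae1.3 and epb41b, −1.96 ± 0.42, adjusted p = 0.0266) and 27 not passed among 29, with 9 down adjusted over the list alone. Their median was −0.66 (camera adjusted p = 0.000112, and adjusted p = 0.234 with an estimated correlation), and −0.36 without sema6A replicate 1.

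All 13 eye field and optic vesicle genes were lower in sema6A than in plexinA2 morphants, with none past the threshold over all rows or adjusted over the list alone. The median was −0.79 (camera adjusted p = 0.000663, and adjusted p = 0.0304 with an estimated correlation), and −0.64 without sema6A replicate 1. The score was 0.31 ± 0.16 in plexinA2 morphants against −0.48 ± 0.10 in sema6A morphants (SD, n = 4). The retinal gene RORB was −0.81 ± 0.31 (adjusted p = 0.122).

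Axon guidance genes were 0 up, 1 down and 21 not passed among 22, with 9 down adjusted over the list alone. The netrin gene NTN1 fell (−1.35 ± 0.30, adjusted p = 0.0368). The median was −0.74 (camera adjusted p = 4.39e-06, and adjusted p = 0.234 with an estimated correlation). Of 15 semaphorins, plexins and neuropilins none passed, and 4 fell adjusted over the list alone, with PLXNB1 at −1.18 ± 0.31 (adjusted p = 0.0535). Their median was −0.68 (camera adjusted p = 0.000419, and adjusted p = 0.2505 with an estimated correlation). Notch and neurogenesis genes were 1 down (MYT1, −1.75 ± 0.36, adjusted p = 0.0235) and 14 not passed among 15, with 6 down adjusted over the list alone (median −0.57, camera adjusted p = 0.00530, and adjusted p = 0.201 with an estimated correlation). Epidermis, hatching gland and notochord genes were 1 down (MATN4) and 16 not passed among 17, with 4 down adjusted over the list alone (median −0.54, camera adjusted p = 0.00167, and adjusted p = 0.194 with an estimated correlation). Of the 13 interferon genes none passed, over all rows or adjusted over the list alone (median −0.64, camera adjusted p = 0.0371, and adjusted p = 0.223 with an estimated correlation). That call was lost in 5 of 12 fits without 1 array (largest adjusted p = 0.0925, without sema6A replicate 1).

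Stress genes (median 0.46, adjusted p = 0.0922), lens genes (−0.41, adjusted p = 0.114), somite segmentation (−0.24, adjusted p = 0.456) and neural crest (−0.07, adjusted p = 0.689) did not pass between the morphants, and no gene of theirs did over all rows or adjusted over the list alone. Nor did cell cycle (median 0.05, mean −0.03, adjusted p = 0.973) or yolk (−0.11, adjusted p = 0.973). Without sema6A replicate 1 the medians were −0.42 for somites, 0.11 for neural crest, −0.01 for cell cycle and −0.30 for yolk.

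The count of 88 moved in both directions with the arrays fitted. It was 6, 15, 8 and 6 without plexinA2 replicates 1 to 4 in turn, and 157 (57 up, 100 down), 15 and 10 without sema6A replicates 1 to 3. It was 495 (202 up, 293 down) without control replicate 2, 248 without control replicate 4, 880 without control replicate 2 and sema6A replicate 1, 743 (296 up, 447 down) when only the 8 morphant arrays were fitted, 58 with 1 row per symbol and 2273 with array weights. All 88 genes were among the 743, and rlbp1b and SRPRA were the 2 of the 12 named calls kept without any single array.

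**Figure D3:**
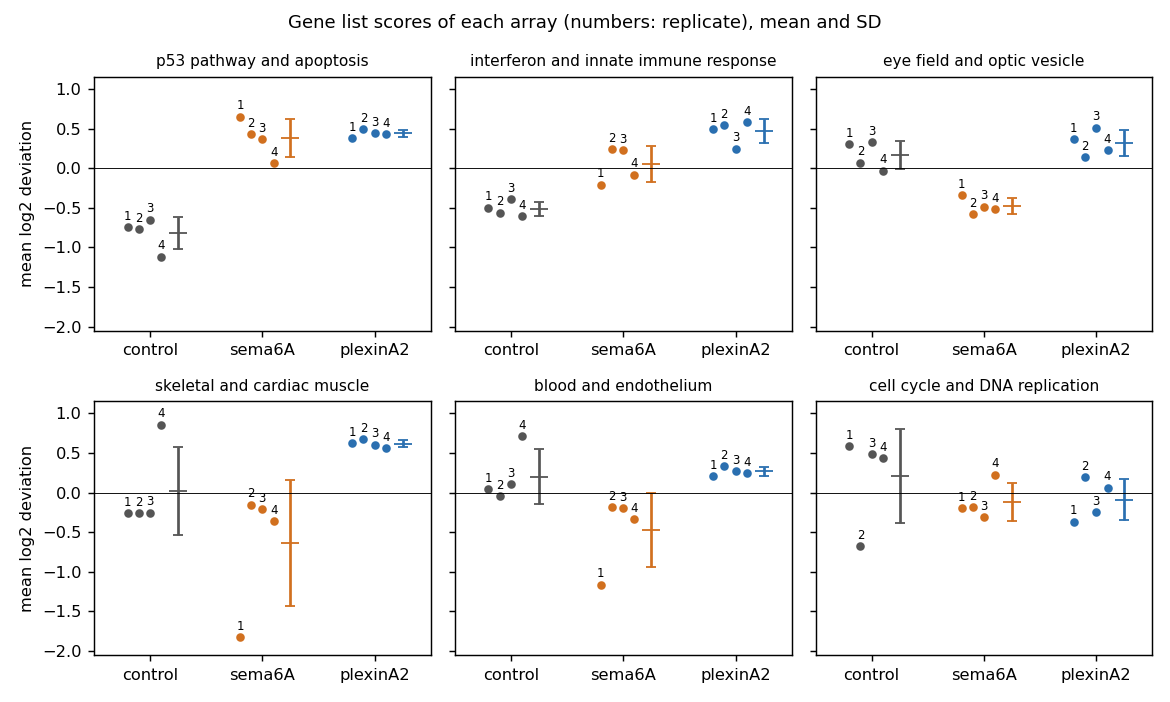
Mean log2 deviation of the genes of 6 lists (vertical axis) in each array, numbered by replicate, with bars for the mean and SD of the 4 arrays per group. All 8 morphant arrays lie above the controls for p53, the sema6A arrays lie below all others for the eye field, and sema6A replicate 1 (−1.82) and control replicate 4 (0.86) mark the ends for muscle.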

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

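Among the tests below, those of injection or morpholino exposure and of an exchanged label, and the use of rank correlation against a difference in distribution, were chosen after the result was seen.

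For 42 of 465 groups of 4 values (named genes, list scores and array measures), 1 array stood far from the other 3 of its group, which chance gives in about 1 of 20 groups. Of the 42, sema6A replicate 1 held 12, control replicate 4 held 11, control replicate 2 held 6, plexinA2 replicate 1 held 5 and sema6A replicate 4 held 4.

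Sema6A replicate 1 stood low in its group for the muscle score (−1.82, the others −0.36 to −0.15) and the blood and endothelium score (−1.16, the others −0.33 to −0.18). Its log2 value of rx3 was 12.44 against 9.66 to 10.10 in the others. It was high for epha2b (12.95), HNF4A (8.196) and bbc3 (11.46). It was low for MEF2C (8.76), SPTB (7.65), MAFA (9.36), PYGM (6.45), PSMB2 (10.31) and MPND (10.40).

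Control replicate 4 stood high in its group for the scores of muscle (0.86, the others −0.26 to −0.25), epidermis with hatching gland and notochord (0.59) and lens (0.37). Its log2 values were high for MATN4 (12.04), FABP7 (10.05), PYGM (10.80) and epb41b (10.51), and low for mespba (9.34), FOXC1 (10.64) and GADD45A (7.11). Control replicate 2 had the lowest mean rank correlation (0.835) and stood low for the cell cycle score (−0.67, the others 0.44 to 0.58) and mical2b (9.48). It was high for lgals3a (10.83), foxd1 (11.82) and FOSL1 (9.60). Control replicate 3 stood apart for LIG1 (12.33) and SEMA4G (9.13).

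Sema6A replicate 4 was low for cdkn2a/b (8.51, the others 10.82 to 11.15), DDIT3 (9.30), LIG1 (11.71) and mat2al (12.52). Sema6A replicate 2 was low for SEMA3F (9.58) and replicate 3 for onecutl (6.001). PlexinA2 replicate 1 was low for nebl (7.57) and EXO5 (11.84) and high for MEF2C (11.81), PSMB2 (13.70) and MIP (6.67).

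The p53 list stood higher in both morphants. With the preset correlation, the largest camera adjusted p of the list over the 12 fits without 1 array and both comparisons was 5.10e-08. That argues against a single array as its whole source. Differences in distribution left after RMA are argued against too, since the larger such p after quantile normalization was 1.05e-12. Both values rest on the preset. With an estimated correlation the list's adjusted p on all arrays was 0.0304 in both comparisons. RMA already normalizes between arrays, so a second normalization cannot test the effect of RMA's own. Of 100 splits of the 12 arrays into 3 groups of 4, only the real split (1 of 100) gave the list as small a p in both comparisons in one direction (−log10 p of 13.5, highest other 8.72). That argues against chance, although 1 of 100 is the smallest share these splits can give. Injection or morpholino exposure as such, rather than loss of either target, predicts like changes in both morphants, and so does loss of a shared pathway. These explanations cannot be told apart here, where no group is labelled as injected with another morpholino, and the median difference of the 10 genes called in both (−0.147, with bbc3 at −0.98 and SESN1 at −1.08) decides nothing between them.

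The muscle list stood lower in sema6A than in plexinA2 morphants. With the preset correlation a single array as the whole source is argued against by the largest adjusted p over the 12 fits without 1 array (4.85e-08), although without sema6A replicate 1 the median moved from −1.21 to −0.83, and with an estimated correlation the list did not pass on all arrays (adjusted p = 0.223). Variation in stage between arrays may underlie it: 85.5% of the squared difference over the 36 genes lay along the deviations of the 4 controls from their own mean, against 8.46% on average (95th percentile 21.3%) for random directions. Genes of a tissue vary together, so random directions are a low bar, and a share this high shows only that untreated arrays varied in the same genes. A delay specific to the Sema6A morpholino stays open and was not tested.

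Control replicate 2 stood apart from all other arrays. An exchange of labels with a morphant array is argued against by its p53 score of −0.771, beside at most −0.649 in the other controls and at least 0.0685 in the morphants (SD 0.163). A difference in the distribution of values alone is argued against by its mean rank correlation of 0.835 (next lowest 0.876, SD of the other 11 arrays 0.0151), since ranks within an array do not depend on the distribution. Its mean Pearson correlation after quantile normalization, 0.837, adds nothing to this, as that step keeps the ranks. No biological explanation was tested, and RNA quality or stage of that sample stay open.

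The splits argue against chance for each count of called genes, as far as so few splits can. A share of 1 of 35 or 1 of 100 is the smallest they can give. Splits that mix the groups also put the group differences into the spread, which lowers their own counts. In fits of only the 8 arrays compared, 1 of 35 splits, the real one, gave as many calls for sema6A against control (47, highest other 2), for plexinA2 against control (132, highest other 0) and for sema6A against plexinA2 (743, highest other 0). Of 100 splits of the 12 arrays, 1, the real one, gave as many genes shared by both comparisons (58, highest other 0). For the number of list calls it was also 1 of 100 (27, highest other 26). The median of the other 99 splits was 13 list calls, and 73 of them gave 10 or more. These splits still hold the group differences in uneven shares, so they do not show how many lists unchanged groups would give.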

How the results depend on the processing

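The fit without control replicate 2 and sema6A replicate 1 was chosen after seeing the data. The planned check of the targeted genes was not run. The cause of each change below was not tested. Some settings hold fewer arrays or rows, and fits of only 2 groups take their spread without the third. The main fit shares 1 spread over groups of unlike tightness. Mean rank correlations within the group were 0.843 to 0.911 for controls and 0.967 to 0.976 for plexinA2 morphants.

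For sema6A against control, the 160 calls became 47 with only the 2 groups compared and 1407 with array weights, and 66 to 226 without single arrays. For plexinA2 against control, the 147 calls became 1629 with array weights, 275 without the 2 arrays of lowest correlation, and 79 to 326 without single arrays. For sema6A against plexinA2, the 88 calls became 743 with only the 2 groups compared, 158 with quantile normalization, 146 with median-centred arrays, 144 with the replicate number as a block, 2273 with array weights, 58 with 1 row per gene symbol, 880 without the 2 arrays of lowest correlation, and 6 to 495 without single arrays. For genes called the same way in both morphants, the 58 became 32 with only the 2 groups compared, 518 with array weights, and 38 to 70 without single arrays. All other planned settings stayed within 1.5 times of these counts.

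With the replicate number as a block (replicate block), the counts were 158, 130 and 144, and 57 for both morphants, with 27 list calls. The numbers did not pair the arrays: 3 of 12 pairs with the same number had a residual correlation over 0.1 (from −0.242 to 0.361), and 3 of 12 arrays correlated best with their own number.

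Of 48 list tests, 27 were called with the preset correlation and 24 to 27 without single arrays. With an estimated correlation 5 were called, p53 in both morphants against control, the eye field in sema6A morphants against control and against plexinA2 morphants, and interferon in plexinA2 morphants, and with fry 18. Of 83 called results of named genes, 44 were called under every alternative, 39 were lost under at least 1, and none changed sign. Without single arrays, 23 of 34 named calls were kept for sema6A against control, 22 of 37 for plexinA2 against control and 2 of 12 between the morphants.

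RMA leaves no signal over background to judge dim genes by. In simulated data, changes of 1 on the log2 scale were mostly missed. They were called in 36.8% of 68 rows for sema6A and 26.4% of 53 rows for plexinA2. Both runs used the same spread, so these shares show no difference between the morphants. The real arrays differed in spread, so the shares need not hold for them.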

Other observations

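The gene groups and genes here were chosen after their values were seen, and every test here was made on the same data.

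Collagen genes, grouped by the symbol prefix COL, were lower in sema6A than in plexinA2 morphants in 22 of 23 genes, with a median of −0.99 (camera adjusted p = 2.89e-07 over 129 tests of 43 prefixes, and adjusted p = 0.965 with an estimated correlation). COL11A2, a fibrillar collagen gene of cartilage, fell in that comparison (−1.96 ± 0.47 SE, n = 4 per group, limma adjusted p = 0.0435). COL12A1, a collagen gene of tendon and fascia, rose in plexinA2 morphants against control (1.58 ± 0.38, adjusted p = 0.0244). The type I collagen gene COL1A1 was −1.87 ± 0.54 between the morphants (adjusted p = 0.0664). Against control the collagen median was −0.46 in sema6A morphants and 0.34 in plexinA2 morphants. Genes of the large mitochondrial ribosome subunit (prefix MRPL) were lower in plexinA2 morphants than in controls in 15 of 15 genes, with a median of −0.40 (camera adjusted p = 0.0213, and adjusted p = 0.965 with an estimated correlation).

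Outside the fixed lists, casp21 and LECT2 stood higher in plexinA2 than in sema6A morphants. The caspase gene casp21 rose by 2.64 ± 0.31 in plexinA2 morphants (adjusted p = 3.00e-05) and was 0.63 ± 0.31 in sema6A morphants (adjusted p = 0.262), and the direct difference was −2.01 (adjusted p = 0.00379). LECT2, a leukocyte chemotaxin gene, rose by 2.25 ± 0.30 in plexinA2 morphants (adjusted p = 0.000141), with a direct difference of −1.99 (adjusted p = 0.00379). The antigen presentation gene b2m rose in plexinA2 morphants (2.41 ± 0.43, adjusted p = 0.00274) and cd40 in both (1.57 ± 0.37, adjusted p = 0.0259, and 2.84 ± 0.37, adjusted p = 9.80e-05). For b2m (adjusted p = 0.126) and cd40 (adjusted p = 0.0669) the morphants did not differ past the threshold.

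The eye field gene rx3 varied widely within the control and sema6A groups. Its log2 values were 11.76, 10.44, 12.66 and 9.20 in the controls and 12.44, 9.76, 10.10 and 9.66 in the sema6A morphants, but 11.81, 11.34, 11.87 and 11.47 in the plexinA2 morphants. By contrast rlbp1b lay between 8.35 and 9.14 in the plexinA2 arrays and between 5.15 and 6.14 in the other 8, with no overlap.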
